A study of Drosophila melanogaster with 80 samples.

How the data were processed

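RNA was taken from hand-dissected or sorted tissue of wandering third-instar larvae and sequenced as TruSeq libraries, per the labels. The authors deposited raw read counts per FlyBase gene in 3 tables, with whole numbers for 15348 genes, and a table of variance-stabilized values on an approximately log2 scale made by the authors with an unstated offset. Per the submitters' processing notes the tools were HTSeq, with no version, edgeR 2.4.6, DESeq 1.6.1 and R 2.14.0, with no role given to each. The aligner, genome build and annotation are not given in the sources used here, so no coordinates are reported. Per the labels and the column names, technical replicates of some samples were pooled into 1 column by the authors.

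The main count table holds the wing discs, brains, driver controls, sorted cells and perturbed discs, and 70 of its columns were used. A separate table holds the wild-type eye-antennal discs and the onecut mutant, and another the eya-sorted cells, whose negative column was checked to equal that of the main table. There were 2 columns of the main table without a matching description, and these were left out. The labels call 1 wild-type eye-antennal stock RAL-208 while its column is named RAL-80, and the column name is used here. Titles mark the wild-type eye-antennal discs and 1 glass mutant stock, the one without FRT, as reanalyzed. The labels list 2 eya-positive samples but the table has 1 positive column, and its name does not say which of them it holds. The control called m4-Gal4 here is titled GMR27H09-Gal4, and its stock is that of the crosses titled m4-Gal4. The slp1 library was taken as RNAi from the TRiP line in its genotype, while its title does not say RNAi. The library of GMR-Gal4 with UAS-GFP has a label that names cell sorting but a title with no sign of the gate, so it entered no main comparison.

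Depth was taken as the total count per library and ran from 3932059 to 39796996. Counting intervals are 95% intervals, a count of 0 allows up to 3 counts, and both cover counting error only. Libraries were checked for identical columns, and 0 pairs were identical; the highest correlation was 0.986, between the side RNAi and toy libraries with GMR-Gal4.

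Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with at least 1 CPM in at least 2 libraries of a fit were kept, counts were scaled by TMM, and differences were tested with the edgeR quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change over the square root of F. The wild-type tissues formed 1 fit, the sorted cells another, all whole-disc libraries another and the onecut table another. Single libraries without a replicate took their spread from the replicated groups of the fit, so each was assumed to vary like those groups. Targeted genes were tested as a family of their own with the same tool. The eya columns, with 1 library per sign, were given as ratios with counting intervals and no test, and list medians were ranked among 10000 random lists of genes with a sum of at least 10 counts, with a pseudocount of 0.5.

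Before the data were examined, 26 gene lists with 336 entries were fixed, of which 335 were found in the table. They cover photoreceptor differentiation, neuronal and synaptic genes, R8 and proneural genes, the furrow, the EGFR pathway, Notch response genes of the E(spl) and Bearded complexes, retinal determination, cone and interommatidial cells, phototransduction, antenna, wing disc, Hox, neuroblast, glia, hemocyte, fat body, muscle, trachea, salivary gland, ecdysone and age, heat shock, cell cycle, stress and death, antimicrobial, ribosomal protein and male dosage compensation genes. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. All 123 list calls of the tissue, sorted-cell, onecut and multi-library perturbation comparisons were lost with an estimated correlation. Member counts are given over all genes and adjusted over the list alone.

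Genes named in each comparison follow a rule fixed at the same time. It takes the targeted gene, the 10 largest rises and 10 largest falls among genes past the threshold with an average log2 CPM of at least 4 and no overlap between groups, and up to 4 members with the smallest adjusted p of each called list, or 2 where each arm had 1 library. The text names a selection of these, together with genes outside the rule where few were called. Relations of 11 regulators with the photoreceptor list used log2 of TMM-scaled CPM plus 0.5 and two-sided permutation tests with 100000 permutations.

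The pipeline was tested on simulated data with the same designs, in which 200 genes were changed, 50 for each of 4 sizes. For eye-antennal against wing discs, 78% of 4-fold rises and 22% of 2-fold rises were recovered with 8 false calls, and for GMR cells 76% and 2% with 10 false calls. For sens cells with 1 library per arm 10% of 4-fold rises were recovered. For reduced glass the shares were 94% and 72% with 5 false calls. For single perturbed libraries, simulated for the rn mutant stock only, they were 82% and 28% with 5, and for onecut 90% and 56% with 45. A doubled cell cycle list was the only list called of 25. Simulated libraries shared the same mean per gene, apart from the changed genes, and varied gene by gene. Differences between libraries that many genes share, such as tissue content, were left out, so the shares may overstate recovery in the real data.

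Alternatives tried were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no filter on low counts, limma on the deposited variance-stabilized values, other sets of controls, fits restricted to the compared libraries, strain or title number as a block, an estimated correlation in the list test, a rank test for targets, and leaving out each library in turn. Added after seeing the data were fits with 4 controls without the wild-type libraries, fits with a term for 13 whole-disc libraries under 100 mitochondrial CPM, 4 driver libraries in place of the wild-type discs, and the comparison of the glass mutant stocks alone. Marker lists for the ring gland and for nuclear-encoded respiratory genes were also added after the data were seen.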

Results

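The data are RNA sequencing counts per gene from third-instar larvae of Drosophila melanogaster, collected to follow how transcription factors shape the developing eye. The eye-antennal disc is the larval epithelium that forms the retina, the antenna and parts of the head. The labels list 80 samples, and 74 libraries entered the work. There were 4 libraries of wild-type wing discs and brains, 6 control libraries of whole eye-antennal discs, 52 libraries of whole discs with a perturbed transcription factor or cell-surface gene, 10 libraries of sorted disc cells, 1 onecut mutant library and 1 library of an unspecified preparation. The controls were 2 wild-type libraries, 3 with only a Gal4 driver (m4-Gal4, GMR-Gal4 and ato-Gal4) and 1 of sens-Gal4 with UAS-GFP. The perturbed libraries were 10 of mutant stocks with 9 targets, 27 of overexpression with 20 targets and 15 of RNAi with 14 targets.

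Total counts ran from 3932059 to 39796996 per library with a median of 10336106. The ranges were 4069012 to 20121224 for the wild-type tissues, 5186557 to 8900168 for the sorted cells, 9498224 to 13602070 for the controls and 3932059 to 39796996 for the perturbed discs. Nothing in the labels states that replicates came from separate animals, so every p-value measures only the spread between these libraries. Values below are log2 fold changes with standard errors, and counts scaled to library size (CPM) as mean and SD over libraries. Lists given below in short form as called lower or higher had no member past the threshold over all genes. Their brackets hold the median, the members past it when adjusted over the list alone, and the p with an estimated correlation.

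The first comparison asks which genes set the eye-antennal disc apart from the wing disc, with 2 wild-type libraries of each. Titles mark both eye-antennal libraries as reanalyzed and no wing disc or brain library. Tissue and source of the data therefore cannot be told apart here. Genes of photoreceptor development were higher in the eye-antennal disc. The receptor tyrosine kinase gene sevenless (sev, FBgn0003366), which acts in R7 photoreceptor choice, rose by 5.54 ± 0.40, from 5.79 ± 3.45 CPM in wing discs to 293 ± 34.4 CPM (adjusted p = 0.001752). The zinc-finger gene glass (gl, FBgn0004618), required for photoreceptor differentiation, rose by 5.76 ± 0.93, from 3.9 ± 5.16 to 260 ± 44.7 CPM (adjusted p = 0.02177). The Pax6 gene twin of eyeless (toy, FBgn0019650) rose by 6.13 ± 0.76, to 271 ± 14.0 CPM. In the other direction, the wing selector gene vestigial (vg, FBgn0003975) fell by 4.69 ± 0.64 on the log2 scale, from 268 ± 85.6 CPM in wing discs to 10.4 ± 7.65 CPM (adjusted p = 0.01148), and the wing-hinge POU gene nubbin (nub, FBgn0085424) fell by 4.02 ± 0.41, from 349 ± 36.1 to 21.5 ± 11.7 CPM (adjusted p = 0.00426).

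Of the 19 measured photoreceptor differentiation genes, 18 rose, and 18 also rose when adjusted over the list alone, with a median of 3.58. Examples were oc at 5.98 ± 0.35, phyl at 3.11 ± 0.25 and the neuronal RNA-binding gene elav at 2.23 ± 0.14. The list call had an adjusted p = 2.923e-14 with the preset correlation and an adjusted p = 0.3299 with an estimated correlation. Of 20 neuronal and synaptic genes 17 rose, and 17 adjusted over the list alone, with nrv3 at 4.70 ± 0.33, Appl at 4.59 ± 0.28 and Syn at 4.53 ± 0.26 (adjusted p = 0.3299 with an estimated correlation). Retinal determination genes, the network that specifies eye fate, held 8 rises and 1 fall among 12, the same numbers adjusted over the list alone, among them ey at 4.70 ± 0.18, eya at 3.36 ± 0.27 and dac at 2.32 ± 0.14 (adjusted p = 0.3874 with an estimated correlation). R8 and proneural genes held 5 rises among 10, or 7 adjusted over the list alone, led by ato at 5.06 ± 0.25, with sca at 0.76 ± 0.14 (adjusted p = 0.3299 with an estimated correlation). In the wing disc list 12 of 18 genes fell and none rose, and 16 fell and 1 rose adjusted over the list alone, with ap at -3.00 ± 0.29 and the Iroquois gene ara at -2.01 ± 0.20 (adjusted p = 0.3299 with an estimated correlation).

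Further lists that the test called higher were glia (8 of 12 rose, and 8 adjusted over the list alone, with Mdr65 at 3.99 ± 0.37 and repo at 3.92 ± 0.41, adjusted p = 0.3299 with an estimated correlation) and hemocytes, the larval blood cells (3 of 13 rose, and 3 adjusted over the list alone, with Pxn at 2.15 ± 0.35, adjusted p = 0.4989 with an estimated correlation). Neuroblast genes held 4 rises among 8, or 5 adjusted over the list alone, with mira at 3.22 ± 0.15 (adjusted p = 0.3874 with an estimated correlation). The EGFR pathway held 6 rises and 1 fall among 13, the same adjusted over the list alone, with the protease gene ru at 5.19 ± 0.38 (adjusted p = 0.4989 with an estimated correlation). Cone and interommatidial cell genes held 5 rises and 1 fall among 7, likewise adjusted over the list alone, and the Notch response genes of the Enhancer of split and Bearded complexes held 5 rises and 1 fall among 15, or 11 and 1 adjusted over the list alone, with HLHmgamma at 3.51 ± 0.24. Phototransduction genes held 4 rises among 11, equal to the count adjusted over the list alone, with eys at 4.01 ± 0.17. Hox genes held 4 rises and 2 falls among 8, or 5 and 2 adjusted over the list alone, with Scr at 4.95 ± 0.55 and Ubx at -2.07 ± 0.27. For these 4 lists the adjusted p = 0.3874 with an estimated correlation. Lists called lower were cell cycle genes (3 of 27 fell, or 4 falls and 1 rise adjusted over the list alone, with RnrS at -0.55 ± 0.10, adjusted p = 0.3874 with an estimated correlation) and ribosomal protein genes (0 of 14 changed by either adjustment, median -0.14, adjusted p = 0.7854 with an estimated correlation). Antenna, antimicrobial, ecdysone and age, fat body, furrow, heat shock, muscle, salivary gland, stress and death, and trachea lists were not called, and the furrow list had a median of 0.02 with a test in the downward direction. The 2 dosage compensation RNAs of the male X chromosome had a median of 0.69, were not called and are too few for the list test.

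Genes of ecdysone synthesis, which is a task of the ring gland beside the brain, also stood among the largest rises: spok (FBgn0086917) rose by 8.53 ± 0.36, from 1.02 ± 0.376 CPM in wing discs to 338 ± 45.7 CPM, and sad (FBgn0003312) by 6.19 ± 0.42. The brain libraries held spok at 354.6 to 494.9 CPM, and the 9 sorted-cell libraries of the main table at 0.999 CPM or less. Whether the neuronal, glial, neuroblast and Hox rises come from disc cells or from tissue dissected with the discs was not tested. In all, 930 genes rose and 99 fell, 1029 of 9474 tested. The count was 598 without the wild-type eye-antennal library whose column is named RAL-80, 666 without the Canton S one, and 673 when only these tissues entered the fit.

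**Figure D1:**
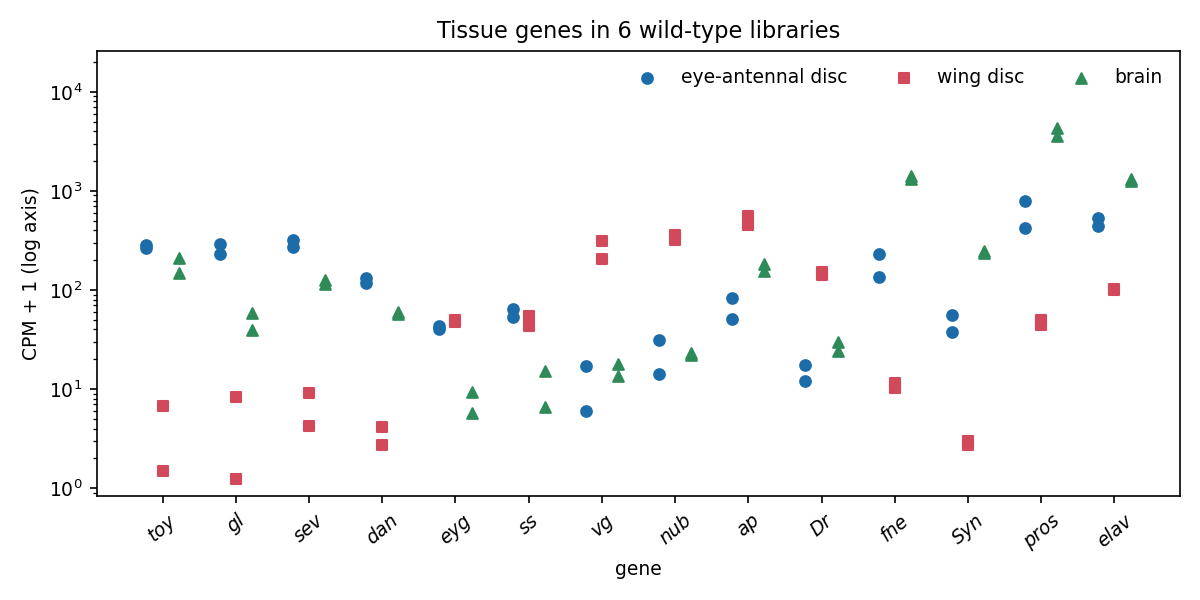
CPM plus 1 (log axis) of 14 genes in the 6 wild-type libraries of eye-antennal disc, wing disc and brain, 1 point per library. Genes such as sev and gl sit above the wing disc points in the eye-antennal disc, and vg and nub lie highest in the wing disc.

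The comparison of eye-antennal disc and brain, again with 2 libraries each, asks what separates the eye primordium from the central nervous system. In this comparison too, tissue and source of the data cannot be told apart. Among the genes higher in the disc, the Pax gene eyegone (eyg, FBgn0000625) rose by 2.65 ± 0.30, from 6.42 ± 2.61 CPM in brain to 40.5 ± 2.09 CPM, and hedgehog (hh, FBgn0004644), the signal that drives the furrow, rose by 1.87 ± 0.14, from 17.6 ± 2.18 to 64.2 ± 4.92 CPM. The R8 proneural gene atonal (ato, FBgn0010433) rose by 2.13 ± 0.20, from 15.7 ± 0.15 to 69.1 ± 9.02 CPM (adjusted p = 0.005795). Among those lower in the disc, the neuronal RNA-binding genes fne (FBgn0086675) fell by 2.88 ± 0.27, from 1334 ± 50.1 to 181 ± 65.4 CPM, and elav (FBgn0260400) by 1.39 ± 0.14, from 1266 ± 57.1 to 484 ± 62.7 CPM. The ecdysone synthesis gene spok stood at 354.6 to 494.9 CPM in the brain libraries. It was also high in the disc libraries, as given above, but at or below 0.999 CPM in the 9 sorted-cell libraries of the main table. Whether tissue dissected with the discs altered the neuronal, glial and neuroblast differences below was not tested.

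Furrow genes, active where differentiation sweeps across the retina, held 7 rises among 8, or 8 adjusted over the list alone, with a median of 1.37 (adjusted p = 0.5192 with an estimated correlation). Retinal determination genes held 6 rises among 12, and 6 adjusted over the list alone, with toe at 2.67 ± 0.29, eya at 2.03 ± 0.26 and so at 1.98 ± 0.29. Antenna genes held 5 rises among 8, or 7 adjusted over the list alone, with ss at 2.53 ± 0.47. Notch response genes held 10 rises and 1 fall among 15, or 11 and 1 adjusted over the list alone, with m6 at -2.12 against the rest. Tracheal chitin genes such as Gasp (2.49 ± 0.20) and serp (1.70 ± 0.14) rose with 4 of 6 list members, or 4 rises and 1 fall adjusted over the list alone. EGFR pathway genes held 6 rises among 13, or 7 adjusted over the list alone, and cell cycle genes 6 among 27, or 8 adjusted over the list alone. All of these lists had an adjusted p = 0.5192 with an estimated correlation. Photoreceptor genes held 8 rises and 2 falls among 19, or 10 and 2 adjusted over the list alone, and the falls included elav and pros, which neurons of the brain also express (adjusted p = 0.5343 with an estimated correlation). Neuronal genes held 15 falls among 20, or 17 adjusted over the list alone, with Syn at -2.37 ± 0.20 (adjusted p = 0.5192 with an estimated correlation). Glial genes held 4 falls and 1 rise among 12, or 6 and 1 adjusted over the list alone (adjusted p = 0.5192 with an estimated correlation), and neuroblast genes 4 falls and 1 rise among 8, the same adjusted over the list alone (adjusted p = 0.5343 with an estimated correlation). The test put ribosomal protein genes higher with 0 of 14 called by either adjustment (adjusted p = 0.5343 with an estimated correlation). In all 692 genes rose and 941 fell, 1633 of 9474. This count rested on the wild-type libraries: it was 0 without the Canton S eye-antennal library, 624 without the RAL-80 one, 1036 without the RAL-208 brain and 854 without the Canton S brain. DESeq2 called 2501 genes, and 4 control libraries with drivers in place of the wild-type discs, chosen after seeing the data, gave 2861.

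Between wing disc and brain, the selector genes of the wing marked the disc and synaptic genes the brain. The gene vg was 4.22 ± 0.62 higher, at 268 ± 85.6 against 14.4 ± 3.25 CPM, and nub was 4.04 ± 0.41 higher, at 349 ± 36.1 against 21.1 ± 1.29 CPM. The ecdysone-inducible gene ImpE2 (FBgn0001254) was 3.19 ± 0.25 higher, at 4107 ± 781 against 450 ± 103 CPM. In the brain the vesicular glutamate transporter gene VGlut (FBgn0031424) reached 401 ± 21.3 CPM against 1.34 CPM in wing discs, a difference of -7.84 ± 0.63. The gene spok lay at -8.83 ± 0.36. Of 20 neuronal genes 18 fell, or 19 adjusted over the list alone, and of 12 glial genes 9 fell, or 10 adjusted over the list alone, with repo at -5.25 ± 0.42. Cell cycle genes held 16 rises among 27, and 16 adjusted over the list alone, such as the mitotic kinase gene polo at 1.00 ± 0.13 and Klp61F at 0.99 ± 0.11. For these 3 lists the adjusted p = 0.506 with an estimated correlation. Photoreceptor genes held 12 falls among 19, or 13 adjusted over the list alone, with pros at -6.35 ± 0.40 and elav at -3.62 ± 0.15 (adjusted p = 0.506 with an estimated correlation). The wing disc list held 13 rises and 1 fall among 18, or 14 and 1 adjusted over the list alone (adjusted p = 0.5611 with an estimated correlation), and ribosomal protein genes held 5 rises among 14, or 11 adjusted over the list alone (adjusted p = 0.5856 with an estimated correlation). Neuroblast genes held 6 falls and 1 rise among 8 by either adjustment, phototransduction genes 5 falls among 11, or 6 adjusted over the list alone, and furrow genes 6 rises and 1 fall among 8 by either (adjusted p = 0.5856 with an estimated correlation for each). Hox genes held 5 falls among 8, or 6 adjusted over the list alone (adjusted p = 0.5382 with an estimated correlation), and tracheal genes 5 rises among 6 by either (adjusted p = 0.506 with an estimated correlation). In all 1363 genes rose and 1822 fell, 3185 of 9474.

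Cells sorted by GFP driven with GMR-Gal4, active behind the furrow, were compared with GFP-negative cells, 2 libraries each, to find genes of differentiating retinal cells. Photoreceptor genes were much higher in the positive cells. The cell-surface gene chaoptin (chp, FBgn0000313) rose by 5.77 ± 0.41, from 17.1 ± 3.00 to 934 ± 386 CPM (adjusted p = 0.007161), and sev rose by 4.77 ± 0.29, from 52.3 ± 4.87 to 1422 ± 387 CPM. The Runx gene lozenge (lz, FBgn0002576), which acts in photoreceptor and cone cell fates, rose by 4.49 ± 0.21, from 17.0 ± 2.50 to 384 ± 25.3 CPM. The protein kinase C gene inaC (FBgn0004784) of phototransduction rose by 6.40 ± 0.72, from 1.72 ± 1.22 to 147 ± 76.6 CPM (adjusted p = 0.02507). The hemocyte gene Pxn (FBgn0011828) fell by 6.15 ± 0.96, from 439 ± 367 to 6.17 CPM (adjusted p = 0.04877), and the antennal LIM-homeobox gene Lim1 (FBgn0026411) fell by 3.23 ± 0.30.

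All GMR list calls had an adjusted p = 0.6193 with an estimated correlation. Photoreceptor genes held 15 rises among 19, or 16 adjusted over the list alone, with peb at 4.29 ± 0.22. EGFR pathway genes held 5 rises among 13, or 8 rises and 1 fall adjusted over the list alone, with ru at 5.36 ± 0.46. Phototransduction genes held 3 rises among 16, or 6 rises and 1 fall adjusted over the list alone, and neuronal genes 1 rise among 20, unc-13 at 1.08 ± 0.20, or 8 adjusted over the list alone. Hemocyte genes held 7 falls among 13, or 11 adjusted over the list alone, with a median of -6.17, and the prophenoloxidase gene proPO-A1 lay at -6.73 ± 0.86. Antenna genes held 5 falls and 1 rise among 8, or 7 and 1 adjusted over the list alone, with Dll at -2.50 ± 0.25. Cell cycle genes held 9 falls and 1 rise among 27, or 16 and 3 adjusted over the list alone, with the ribonucleotide reductase genes RnrL at -1.76 ± 0.18 and RnrS at -1.64 ± 0.21. The wing disc list held 4 falls and 2 rises among 18, or 8 and 2 adjusted over the list alone; the rises were salr at 2.98 and salm at 2.69. Glial genes held 2 falls among 12, or 6 falls and 1 rise adjusted over the list alone. The test also put antimicrobial genes lower with 0 of 11 called by either adjustment, and heat shock genes higher with 1 of 14, Hsp67Bc at 2.12 ± 0.24, also 1 adjusted over the list alone. In all 396 genes rose and 299 fell, 695 of 10488. The count was 0 without either positive library, 2135 without negative library 1 and 1894 without negative library 2, and DESeq2 called 1168. With the number in the titles as a block it was 2319, with 1092 rises and 1227 falls, so the balance of directions turned, and the number is not shown to pair the libraries.

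**Figure D2:**
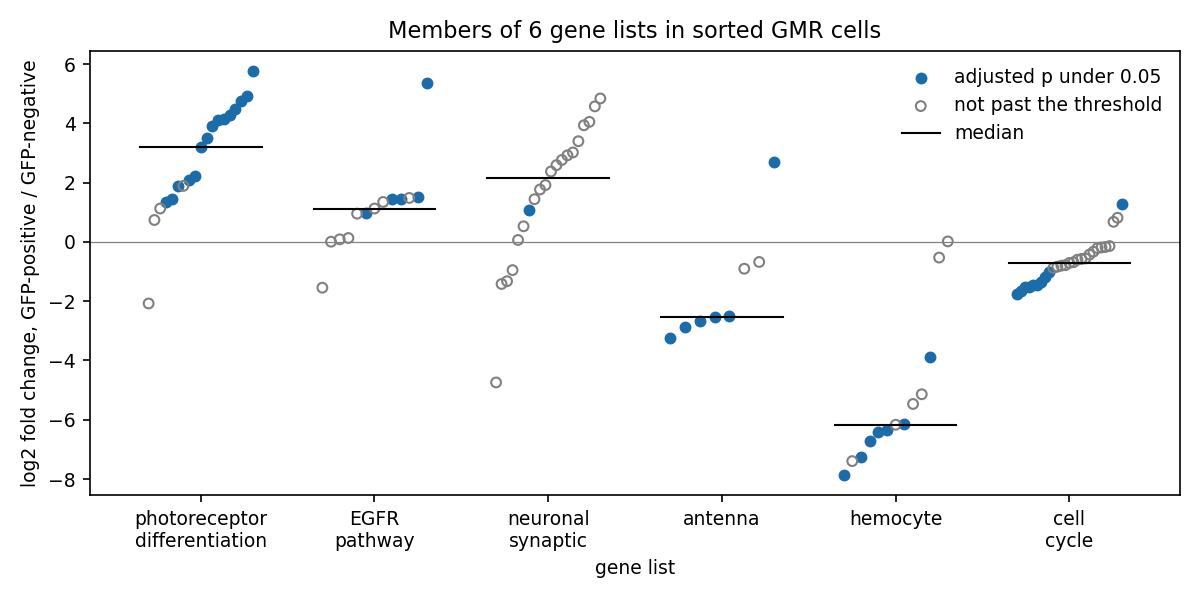
Log2 fold changes between GMR GFP-positive and GFP-negative cells (2 libraries each) of the members of 6 gene lists, 1 point per gene. Photoreceptor genes lie mostly above 0 and hemocyte genes below it.

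GFP-positive cells of the sens line, which marks R8 precursors, and of the chp line, a photoreceptor marker, had 1 library per sign, and each lone library was assumed to vary like the replicated groups. No gene passed in either comparison with the edgeR quasi-likelihood test. In the sens comparison 1287 genes had an unadjusted p under 0.05 and DESeq2 called 332, or 55 with edgeR when no filter on low counts was applied, and in the chp comparison these numbers were 2110 and 537. The senseless gene (sens, FBgn0002573) itself held 542 counts in the positive and 92 in the negative library, 2.90 ± 0.43 (adjusted p = 0.1175), and the R8 ligand gene boss 56.7 and 0.978 CPM. The list test put photoreceptor genes higher in sens-positive cells, with a median of 2.56 over 19 genes, 0 called over all genes and 16 rises adjusted over the list alone, such as peb at 2.92 ± 0.29 (adjusted p = 0.7333 with an estimated correlation). R8 and proneural genes had a median of 1.05, with 4 rises and 1 fall adjusted over the list alone, and antenna genes a median of -3.63, with 7 falls and 1 rise adjusted over the list alone (adjusted p = 0.7333 with an estimated correlation for both). Called lower in sens-positive cells was hemocyte (-3.34, 1 fall of 13, adjusted p = 0.7378 with an estimated correlation). Also lower were antimicrobial (-1.56, 0 of 11, adjusted p = 0.7333 with an estimated correlation) and wing disc (-1.33, 1 rise and 2 falls of 18, adjusted p = 0.7333). Called higher in sens-positive cells was EGFR pathway (1.02, 6 rises of 13, adjusted p = 0.7333 with an estimated correlation). Also higher were neuronal (2.93, 0 of 20, adjusted p = 0.7378 with an estimated correlation) and phototransduction (1.36, 0 of 16, adjusted p = 0.7333). Also higher were Notch response (0.68, 0 of 15, adjusted p = 0.7378 with an estimated correlation) and heat shock (0.91, 0 of 14, adjusted p = 0.7378). In chp-positive cells chp measured 1374 CPM against 33.3, 5.37 ± 0.56 (adjusted p = 0.1018). Photoreceptor genes there had a median of 0.81 with 5 rises adjusted over the list alone, ribosomal protein genes a median of 1.02 with 5, and salivary gland genes a median of -4.62 over 6 measured with 4 falls (adjusted p = 0.9887 with an estimated correlation for each). The salivary glue gene Sgs3 held 6 counts in the chp-positive and 368 in the chp-negative library. Positive-to-negative differences were also compared between drivers: 0 genes differed between GMR and sens (197 with an unadjusted p under 0.05), 0 between GMR and chp (2569) and 0 between sens and chp (1943) by edgeR, and no other tool was run on these.

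Reduced glass was examined in 3 libraries, a gl60j mutant stock, an FRT gl60j mutant stock and a glass RNAi library, against the 6 controls, to find genes that depend on this regulator. The Notch response gene m2 (FBgn0002592) rose by 0.89 ± 0.14, from 88.6 ± 8.89 to 164 ± 51.4 CPM (adjusted p = 0.02597), and CG4038 (FBgn0011824) rose by 0.55 ± 0.09, from 72.8 to 107 CPM. The genes metro (-1.16 ± 0.17) and CG17739 (-2.33 ± 0.39) fell; they lie outside the naming rule and were picked after their values were seen. The level of gl was 122 CPM against 254.5 ± 45.3 CPM, -1.06 ± 0.29 (adjusted p = 0.115). Notch response genes held 1 rise among 15, or 5 adjusted over the list alone, with a median of 0.41 (adjusted p = 0.2622 with an estimated correlation). Photoreceptor genes had a median of -0.60, with none called over all genes and 9 falls and 3 rises among 19 adjusted over the list alone (adjusted p = 0.4702 with an estimated correlation), and neuronal genes a median of -1.35, with 9 falls adjusted over the list alone (adjusted p = 0.3224 with an estimated correlation). The fat body list, larval serum protein genes of another tissue, had a median of -2.88 with 0 of 7 called by either adjustment (adjusted p = 0.6182 with an estimated correlation), and heat shock genes a median of 1.10 with 0 of 13 (adjusted p = 0.5876 with an estimated correlation). The heat shock list averaged 6.70 in the RNAi library, 4.77 in the gl60j stock and 4.21 in the FRT gl60j stock on the log2 scale, against 4.167 to 5.15 in the controls. Called lower with reduced glass were glia (-0.69, 0 of 12, adjusted p = 0.2622 with an estimated correlation) and phototransduction (-0.76, 1 fall of 16, adjusted p = 0.3224). Called higher with reduced glass was retinal determination (0.41, 0 of 12, adjusted p = 0.4702 with an estimated correlation). Also higher were furrow (0.35, 4 rises of 8, adjusted p = 0.3383 with an estimated correlation) and antenna (0.46, 1 rise of 8, adjusted p = 0.4702). Also higher were trachea (0.44, 2 rises of 6, adjusted p = 0.3078 with an estimated correlation) and stress and death (0.33, 0 of 15, adjusted p = 0.5876). In all 2 genes rose and 2 fell among 10393, while 2006 had an unadjusted p under 0.05 and DESeq2 called 179 higher and 566 lower. Leaving out 1 library gave 9 (m4-Gal4 driver), 1 (GMR-Gal4 driver), 40 (ato-Gal4 driver), 0 (sens-Gal4 with UAS-GFP), 1 (wild type RAL-80), 1 (wild type Canton S), 30 (gl60j stock), 0 (FRT gl60j stock) or 193 (RNAi library) genes. The count was 0 in a fit of only these libraries and 35 with only the wild types as controls. It was 16 with the GMR-Gal4 with UAS-GFP library among the controls, and 344 rises and 93 falls, the opposite balance to DESeq2, with all whole-disc libraries of other targets among them.

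The mutant stocks alone, 2 libraries against 6 controls, were compared as an addition after the data were seen. Among the genes that fell were chp by 3.71 ± 0.39, from 147 ± 50.5 to 11.2 ± 2.49 CPM, boss by 3.57 ± 0.33, inaC by 7.47 ± 0.52, from 31.9 to 0.180 CPM, and CG9935 (FBgn0039916) by 5.98 ± 0.38, from 46.7 ± 12.6 to 0.730 CPM. The level of gl fell by 1.69 ± 0.26, to 78.8 ± 41.5 CPM (adjusted p = 0.001983). Notch response genes held 5 rises among 15, or 9 adjusted over the list alone, with m2 at 1.02 ± 0.15, Brd at 1.01 ± 0.20 and m4 at 0.98 ± 0.21, and retinal determination genes 2 rises among 12, or 8 adjusted over the list alone, dan at 0.94 ± 0.22 and Optix at 0.64 ± 0.15. Phototransduction genes held 2 falls among 16, or 5 adjusted over the list alone. For these 3 lists the adjusted p = 0.3443 with an estimated correlation. Photoreceptor genes held 2 falls and 1 rise among 19, or 9 and 4 adjusted over the list alone, and the rise was the Bar homeobox gene B-H2 at 1.03 (adjusted p = 0.5666 with an estimated correlation). Stress and death genes had a median of 0.45 with 0 of 15 called by either adjustment (adjusted p = 0.5428 with an estimated correlation). Called lower in the stocks was neuronal (-1.12, 7 falls of 20, adjusted p = 0.5666 with an estimated correlation). Called higher in the stocks were furrow (0.55, 3 rises of 8, adjusted p = 0.3443 with an estimated correlation) and antenna (0.48, 3 rises of 8, adjusted p = 0.5666). In all 81 genes rose and 77 fell, 158 in total. Apart from the estimated correlation for the lists, no alternative was run for this comparison.

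Overexpressed glass, with hs-Gal4 and GMR-Gal4 (1 library each) against 6 controls, raised gl by 1.72 ± 0.30, from 254.5 ± 45.3 to 841 ± 134 CPM (adjusted p = 0.03026). The gene CG12730 (FBgn0029771) rose by 0.81 ± 0.14. The mitochondrial transcript mt:CoI (FBgn0013674) fell by 6.63 ± 1.26, from 968 ± 635 to 9.79 CPM, and both libraries belong to 13 whole-disc libraries with few mitochondrial counts. Heat shock genes had a median of 3.78, with 0 of 13 called over all genes and 12 rises adjusted over the list alone (adjusted p = 0.3481 with an estimated correlation). Only the hs-Gal4 library stood above the controls in this list, with an average of 7.68 on the log2 scale, while the GMR-Gal4 library had 4.51 and the controls 4.167 to 5.15. Hsp26, scaled by total counts, measured 7007 CPM with hs-Gal4 and 179 CPM with GMR-Gal4, against 141.3 to 312 CPM in the controls. Ribosomal protein genes had a median of 0.54 with 6 of 14 rises adjusted over the list alone (adjusted p = 0.4125 with an estimated correlation), neuronal genes -0.98 with 0 of 20 called by either adjustment (adjusted p = 0.3481 with an estimated correlation), and photoreceptor genes -0.27 with 0 of 19 (adjusted p = 0.444 with an estimated correlation). Called lower with overexpressed glass were glia (-0.84, 0 of 12, adjusted p = 0.3481 with an estimated correlation) and wing disc (-0.57, 0 of 18, adjusted p = 0.3481). Also lower were cone and interommatidial cell (-0.45, 2 falls of 7, adjusted p = 0.3481 with an estimated correlation) and furrow (-0.28, 0 of 8, adjusted p = 0.444). Also lower were R8 and proneural (-0.29, 0 of 10, adjusted p = 0.444 with an estimated correlation) and EGFR pathway (-0.35, 0 of 13, adjusted p = 0.5174). Called higher with overexpressed glass were antimicrobial (0.46, 1 rise of 11, adjusted p = 0.3481 with an estimated correlation) and Notch response (0.18, 0 of 15, adjusted p = 0.444). In all 19 genes rose and 1 fell. The count was 10 without the hs-Gal4 library, 1383 without the GMR-Gal4 library and 2 with only the wild types as controls. It was 2 in a fit of only these libraries, 169 with all whole-disc libraries of other targets among the controls, and 115 by DESeq2. With settings chosen after the data were seen it was 0, with 4 controls that leave out the wild types and with a term for few mitochondrial counts, and the gl call ended in both. It was 2 without the m4-Gal4 control, 12 without the GMR-Gal4 control, 4 without the ato-Gal4 control, 1 without the RAL-80 wild type and 2 without the Canton S wild type.

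**Figure D3:**
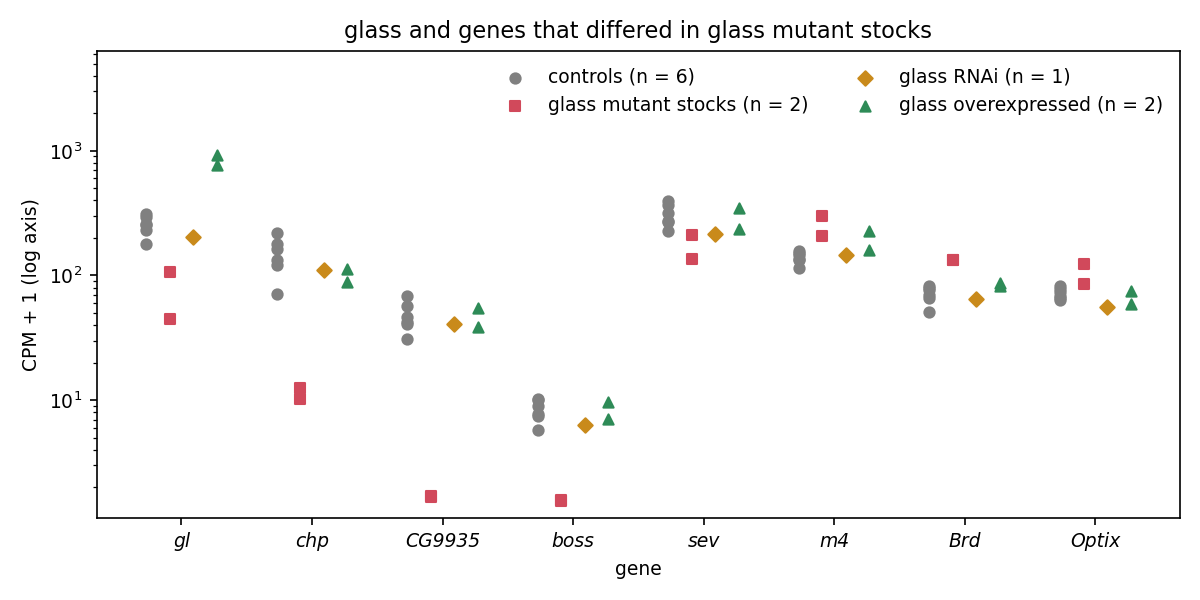
CPM plus 1 (log axis) of gl, chp, CG9935, boss, sev, m4, Brd and Optix in the 6 controls, 2 glass mutant stocks, 1 glass RNAi library and 2 glass overexpression libraries, 1 point per library. The mutant stocks lie below the controls for chp, CG9935 and boss, and the RNAi library lies nearer the controls.

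Overexpression of further regulators, each in 2 libraries with different drivers against the same 6 controls, asks what differs in the disc. For several lists the mean over the controls differed from the mean over the 52 perturbed libraries, which pool all targets. The ranges of the 2 sets overlapped for each list named here, and the differences were not tested. Muscle, for example, ran from 4.36 to 6.29 in controls and from 2.45 to 6.61 in perturbed discs. On the log2 scale the neuronal list had a mean and SD of 5.81 ± 0.73 in controls and 4.81 ± 0.50 in perturbed discs, glia 4.96 and 4.13, Hox 3.09 and 2.15, and muscle 5.12 and 4.33. The fat body list averaged 8.27 and 5.90, salivary gland 4.496 and 2.969, ring gland 5.57 and 4.06, Notch response 5.30 and 5.47, and retinal determination 7.21 and 7.45. A call of these lists in a comparison with these controls, glass and single libraries included, is therefore not shown to follow from its regulator. Optix (FBgn0025360), a retinal determination gene, rose by 3.19 ± 0.19, from 71.2 ± 7.39 to 651 ± 35.2 CPM (adjusted p = 2.519e-08). Also higher were CG17669 and CG31626, both under 1 CPM in the controls. All 3 calls by edgeR were rises, whereas DESeq2 called 9 genes higher and 35 lower with Optix. Neuronal genes had a median of -0.91 with 1 of 20 falls adjusted over the list alone, and photoreceptor genes -0.42 with 1 of 19 (adjusted p = 0.3394 with an estimated correlation for both). Called lower with Optix were Hox (-1.38, 1 fall of 8, adjusted p = 0.3394 with an estimated correlation) and muscle (-0.78, 0 of 15, adjusted p = 0.7785). Also lower were hemocyte (-0.60, 0 of 13, adjusted p = 0.7785 with an estimated correlation) and antimicrobial (-1.73, 0 of 11, adjusted p = 0.5816). The Optix count of 3 genes (465 with an unadjusted p under 0.05) was 44 by DESeq2, 1 with only the wild types as controls, 1 without the GMR-Gal4 control, 1 without the eye-disc-Gal4 library and 12 without the ato-Gal4 library.

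In the Dfd overexpression libraries the head Hox gene Deformed (Dfd, FBgn0000439) rose by 3.96 ± 0.30, from 29.9 ± 4.37 to 466 ± 275 CPM (adjusted p = 1.083e-06). The chitin deacetylase gene serp (FBgn0260653) rose by 1.06 ± 0.19 and the protease gene ste24a (FBgn0034176) fell by 1.17 ± 0.12 (adjusted p = 7.663e-05). Markers of other tissues were low in these libraries: the fat body list had a median of -7.16 with 7 of 7 falls adjusted over the list alone and 0 over all genes, and Lsp2 measured 11.2 ± 5.26 against 2596 ± 2968 CPM (adjusted p = 0.4802 with an estimated correlation). The salivary gland list had a median of -6.64 with 0 of 9 called by either adjustment (adjusted p = 0.4802 with an estimated correlation). Ecdysone and age genes had a median of -0.36 with 0 of 14 called by either adjustment (adjusted p = 0.4917 with an estimated correlation). Called lower with Dfd were glia (-1.71, 2 falls of 12, adjusted p = 0.315 with an estimated correlation) and neuronal (-0.86, 0 of 20, adjusted p = 0.4917). Called higher with Dfd were photoreceptor (0.25, 0 of 19, adjusted p = 0.4917 with an estimated correlation) and retinal determination (0.44, 1 rise of 12, adjusted p = 0.4917). Also higher were Notch response (0.31, 0 of 15, adjusted p = 0.4917 with an estimated correlation) and furrow (0.15, 0 of 8, adjusted p = 0.4917). Also higher were cell cycle (0.19, 0 of 27, adjusted p = 0.4917 with an estimated correlation) and ribosomal protein (0.35, 0 of 14, adjusted p = 0.5198). In all 12 genes rose and 2 fell, whereas DESeq2 called 96 higher and 585 lower. With settings chosen after the data were seen the count was 3 with 4 controls and 2 with a term for few mitochondrial counts. It was 9 with only the wild types as controls, 334 without the lz-Gal4 library, 7 without the hs-Gal4 library, 6, 9 and 8 without the m4-Gal4, GMR-Gal4 and sens-Gal4 controls, and 5 and 6 without the RAL-80 and Canton S wild types.

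In the libraries overexpressing toy and the retinal determination gene distal antenna-related (danr, FBgn0039283), the kinetochore gene Kmn1 (FBgn0027259) was higher by 1.49 ± 0.20 with toy, from 15.3 ± 1.59 to 43.1 CPM, and by 1.61 ± 0.20 with danr, to 46.7 CPM (adjusted p = 0.001288 for danr). Kmn1 also stood at 87.6 CPM in the Dfd mutant stock and 71.6 CPM in the lz mutant stock, and whether it follows from toy or danr was not tested. The genes CG11697, Gr64a and Gr64f passed in each comparison from controls with 3 counts or fewer in each library. As these controls are shared, this agreement does not show a shared effect, and Gr64a and Gr64f passed with so as well. With toy, Neurochondrin and CG14687 fell, by 4.57 and 3.94, and with danr CG5941 (FBgn0029833) rose by 0.88 ± 0.14. The level of toy itself was 638 ± 150 against 262 ± 20.9 CPM, 1.28 ± 0.34 (adjusted p = 0.2241), and that of danr 268.5 ± 159 against 107 ± 13.7 CPM, 1.33 ± 0.28 (adjusted p = 0.134). Muscle genes had a median of -2.75 with toy and -2.89 with danr, with 0 of 15 called over all genes and 10 and 12 falls adjusted over the list alone (adjusted p = 0.2167 and 0.1146 with an estimated correlation). Salivary gland genes had a median of -7.73 with danr, with 8 of 9 falls adjusted over the list alone (adjusted p = 0.2482 with an estimated correlation). Notch response genes were called higher in both although their mean was -0.07 with toy and -0.12 with danr, against medians of 0.33 and 0.34 (adjusted p = 0.3047 and 0.2875 with an estimated correlation). Called lower with toy was fat body (-4.90, 0 of 7, adjusted p = 0.365 with an estimated correlation). Also lower were salivary gland (-5.70, 0 of 9, adjusted p = 0.3047 with an estimated correlation) and Hox (-3.71, 3 falls of 8, adjusted p = 0.2167). Also lower were glia (-1.59, 0 of 12, adjusted p = 0.2167 with an estimated correlation) and neuronal (-1.16, 1 fall of 20, adjusted p = 0.3047). Also lower were neuroblast (-1.31, 1 fall of 8, adjusted p = 0.4786 with an estimated correlation) and antimicrobial (-2.02, 0 of 11, adjusted p = 0.365). Called higher with toy were retinal determination (0.47, 1 rise of 12, toy itself, adjusted p = 0.3047 with an estimated correlation) and cell cycle (0.12, 0 of 27, adjusted p = 0.365). Called lower with danr were fat body (-6.03, 6 falls of 7, adjusted p = 0.2875 with an estimated correlation) and Hox (-3.59, 1 fall of 8, adjusted p = 0.2482). Also lower were neuronal (-0.99, 0 of 20, adjusted p = 0.4445 with an estimated correlation) and neuroblast (-0.87, 0 of 8, adjusted p = 0.4445). Called higher with danr were retinal determination (0.45, 1 rise of 12, danr itself, adjusted p = 0.3619 with an estimated correlation) and photoreceptor (0.29, 0 of 19, adjusted p = 0.4445). Also higher were EGFR pathway (0.15, 0 of 13, adjusted p = 0.4582 with an estimated correlation) and R8 and proneural (0.17, 0 of 10, adjusted p = 0.4445). Also higher were furrow (0.14, 0 of 8, adjusted p = 0.4445 with an estimated correlation) and cell cycle (0.03, 0 of 27, adjusted p = 0.5685). In all 4 genes rose and 2 fell with toy and 5 rose with danr, whereas DESeq2 called 11 higher and 666 lower with toy and 15 higher and 565 lower with danr. With a term for few mitochondrial counts, chosen after the data were seen, the danr count was 0, and the toy count was 2 with only the wild types as controls. Without the GMR-Gal4 or ato-Gal4 toy library the toy count was 1 or 2, and the danr count was 9 without the GMR-Gal4 control and 3 without the m4-Gal4 danr library.

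With so overexpression 3 genes rose, Gr64a, Gr64f and CG7349, each under 1 CPM in the controls, and so itself measured 142 against 132 CPM, 0.11 ± 0.24 (adjusted p = 0.9751). DESeq2 called 5 genes higher and 41 lower with so, the opposite balance. The so count was 46 by DESeq2, 0 with only the wild types as controls, 1 without the GMR-Gal4 control and 0 without the Gal4-7 library, and its fold for so was -0.09 with the GMR-Gal4 with UAS-GFP library among the controls. Neuronal genes had a median of -1.20 with 0 of 20 called by either adjustment (adjusted p = 0.346 with an estimated correlation). Called lower with so was fat body (-4.00, 0 of 7, adjusted p = 0.9648 with an estimated correlation). Called higher with so was Notch response (0.37, 0 of 15, adjusted p = 0.346 with an estimated correlation). With lz overexpression and with side RNAi, 0 genes passed by edgeR, against 846 and 982 with an unadjusted p under 0.05 and 298 and 432 by DESeq2. The lz count was 1 without the sens-Gal4 control and 2 without the lz-Gal4 library. The level of lz was 490 ± 533 against 80.7 ± 13.8 CPM (852.7 CPM with GMR-Gal4 and 117 CPM with lz-Gal4, scaled by total counts), 2.60 ± 0.42 (adjusted p = 0.07424), and that of side, a guidance gene of motor axons, 24.1 against 30.2 CPM, -0.33 ± 0.40 (adjusted p = 0.8736). Muscle genes had a median of -2.40 with lz, with 10 of 15 falls adjusted over the list alone (adjusted p = 0.5971 with an estimated correlation), and cell cycle genes a median of 0.16 with side RNAi, with 0 of 27 called by either adjustment (adjusted p = 0.4843 with an estimated correlation). Called lower with lz was fat body (-5.29, 0 of 7, adjusted p = 0.5971 with an estimated correlation). Also lower were salivary gland (-3.38, 0 of 9, adjusted p = 0.6305 with an estimated correlation) and neuronal (-0.66, 0 of 20, adjusted p = 0.6305). Called higher with lz were Notch response (0.25, 0 of 15, adjusted p = 0.5971 with an estimated correlation) and retinal determination (0.30, 0 of 12, adjusted p = 0.6305). Also higher were ribosomal protein (0.26, 0 of 14, adjusted p = 0.6305 with an estimated correlation) and cell cycle (0.05, 0 of 27, adjusted p = 0.6305). Called lower with side RNAi was salivary gland (-4.67, 0 of 9, adjusted p = 0.5127 with an estimated correlation). Also lower were Hox (-3.09, 0 of 8, adjusted p = 0.4843 with an estimated correlation) and glia (-1.66, 2 falls of 12, adjusted p = 0.4843). Also lower were muscle (-1.45, 0 of 15, adjusted p = 0.5127 with an estimated correlation) and neuroblast (-1.16, 0 of 8, adjusted p = 0.5127). Also lower were neuronal (-1.02, 0 of 20, adjusted p = 0.4843 with an estimated correlation) and stress and death (-0.44, 0 of 15, adjusted p = 0.5127). Called higher with side RNAi were photoreceptor (0.30, 0 of 19, adjusted p = 0.5127 with an estimated correlation) and retinal determination (0.34, 0 of 12, adjusted p = 0.5127). Also higher were Notch response (0.14, 0 of 15, adjusted p = 0.5127 with an estimated correlation) and ribosomal protein (0.20, 0 of 14, adjusted p = 0.5784).

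The remaining 33 perturbations had 1 library each, set against the 6 controls and assumed to vary like the replicated groups. Together they gave 1457 calls, 1117 rises and 340 falls, and 5 libraries had more than 50. With a term for few mitochondrial counts, chosen after the data were seen, 3 libraries did, and the calls went from 129 to 8 for the E(spl) mutant stock, from 79 to 7 for the Su(H) library and from 16 to 1 for the atonal library, which had 6 with 4 controls, a setting chosen likewise. The atonal library raised ato by 2.60 ± 0.21 and its R8 partners sens by 2.07 ± 0.20 and sca by 1.16 ± 0.20, while sev fell by 1.65 ± 0.31; its R8 and proneural list, with the overexpressed ato as 1 of its 3 members that rose, was called with an adjusted p = 0.0184 with an estimated correlation. The other list call of a single library that held was antimicrobial genes in the library labelled sens-2 RNAi, with a median of 1.45, 0 of 11 members called and an adjusted p = 0.01603 with an estimated correlation. The Kr[If-1] stock, a dominant allele of the gap gene Krüppel (Kr, FBgn0001325), had Kr at 419 CPM against 5.86 ± 3.96 CPM and falls in 3 of 19 photoreceptor genes, sev at -2.40 ± 0.32, svp at -2.13 ± 0.32 and the EGFR inhibitor gene aos at -1.52 ± 0.26 (list median -1.48, adjusted p = 0.1043 with an estimated correlation). Its neuronal list had a median of -2.96 with 4 of 20 falls (adjusted p = 0.1426 with an estimated correlation), muscle -2.77 with 1 of 15 (adjusted p = 0.2272), glia -1.55 with 0 of 12 (adjusted p = 0.1043) and fat body -7.31 with 0 of 7 (adjusted p = 0.5477). The library labelled eya RNAi had 348 rises and 22 falls, among the rises the JAK/STAT ligand genes upd2 at 4.97 ± 1.02 and os at 2.56 ± 0.35 and the pathway target Socs36E at 1.01 ± 0.19, and its eya level was -0.06 ± 0.28 relative to controls, or 0.10 against only the wild types. It carries hs-Gal4, as no control does, so driver and target cannot be told apart. In the E(spl) mutant stock E(spl) rose by 3.76 ± 0.15 and ato by 1.39 ± 0.21. The Su(H) library had Su(H) at 4.44 ± 0.13 and repo at 3.61 ± 0.34, and its roX1 and roX2 levels lay at -5.64 ± 1.15 and -6.68 ± 1.29. The rn mutant stock had the most calls, 451 rises and 89 falls, among them the synaptic gene brp at 1.97 and the FGF receptor gene htl at -1.53. Eya overexpression, gsb-n overexpression and the slp1 library had 0 calls by edgeR, against 138, 508 and 307 with an unadjusted p under 0.05.

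Each labelled target was also examined in its own library against the controls. Of 27 overexpression libraries 20 had the target called higher, and all 27 folds were above 0; the largest was Lim3 (FBgn0002023) at 6.26 ± 0.28, 1465 against 19.1 CPM. Those not called were Dip3, lz with lz-Gal4, aop, dan, gsb-n and so with both drivers. By rank among libraries that do not target the gene 16 passed, and repo, toy with both drivers and danr with hs-Gal4 did not (adjusted p = 0.08187, 0.08187, 0.1163 and 0.1922). Of 15 RNAi libraries none had the target called lower, 8 folds lay below 0 and 4 targets were called higher. In the library labelled sens-2 RNAi, sens-2 rose by 4.62 ± 0.27, in the one labelled Lim3 RNAi Lim3 rose by 3.62 ± 0.29, in the one labelled retn RNAi retn rose by 0.89 ± 0.23, and in the slp1 library slp1 rose by 0.46 ± 0.14. The title of that library does not say RNAi. Among mutant stocks, lz fell by 3.67 ± 0.31, sv by 2.50 ± 0.42, gl by 2.36 ± 0.31 in the FRT stock and 1.24 ± 0.28 in the other, ro by 1.59 ± 0.48 and peb by 1.01 ± 0.28, whereas rn was at -1.21 ± 0.57 (adjusted p = 0.07706) and Dfd at 0.24 ± 0.21.

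**Figure D4:**
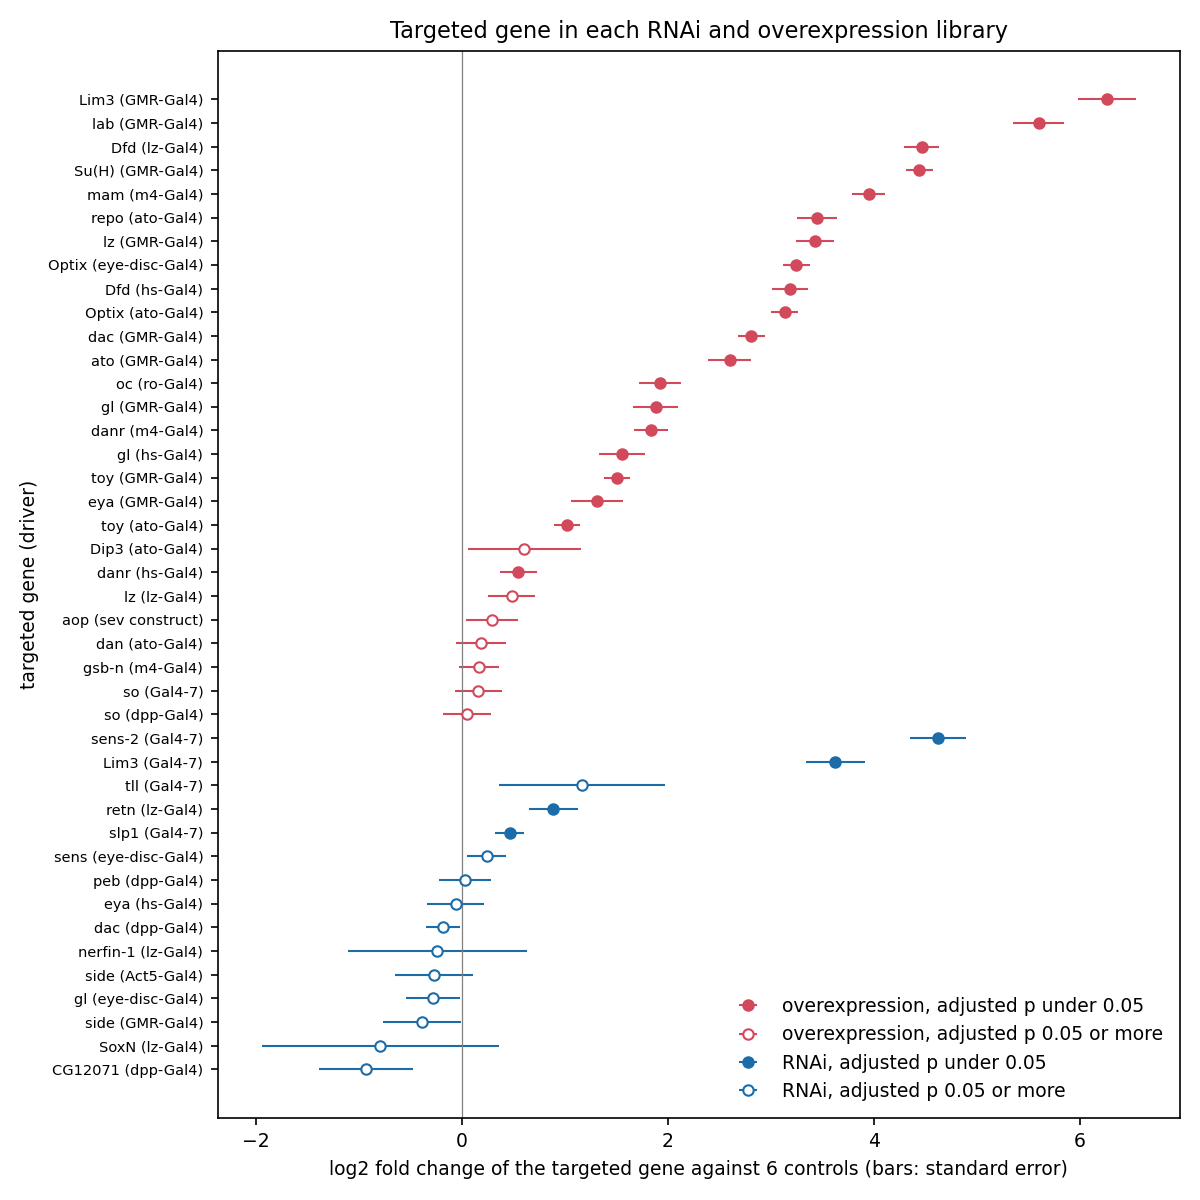
Log2 fold change with standard error of the targeted gene in each of 42 overexpression and RNAi libraries against the 6 controls. All 27 overexpression folds lie above 0, and the highest RNAi folds are those of sens-2 and Lim3.

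Over whole-disc libraries not targeting the regulator, the level of 11 regulators was related to the mean of the photoreceptor list. For peb, the zinc-finger gene hindsight, Pearson's r was 0.746 and Spearman's rho 0.7099 over 56 libraries (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; adjusted p = 3.667e-05 and 2.2e-05), r was 0.606 without the 2 libraries farthest from the median, 0.936 within the 13 libraries with few mitochondrial counts and 0.689 within the 43 others. For gl r was 0.706 and rho 0.682 over 53 libraries (permutation p = 1e-05 for each, adjusted p = 3.667e-05 and 2.2e-05), and r was 0.626 without the 2 farthest, 0.760 within the 42 others and 0.353 within the 11 with few mitochondrial counts (permutation p = 0.287), so the relation was not shown within that group. For ro r was 0.256 and rho 0.0860 (permutation p = 0.05416 and 0.5237, adjusted p = 0.06619 and 0.5237), and r was -0.0156 without the 2 farthest, 0.0776 within the 13 and 0.315 within the 44 others. Pearson's r passed for 8 of the 11 regulators (adjusted p under 0.05), not for toy, dac and ro. Within the libraries with few mitochondrial counts, a set chosen after the data were seen, 3 passed: peb, eya and toy. For toy rho was 0.358 (adjusted p = 0.008751), and without the glass libraries r for ro was 0.364 (adjusted p = 0.01373).

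Levels of a ring gland gene and of mitochondrially encoded transcripts varied widely over the 58 whole-disc libraries. The ring gland gene spok lay between 0 and 525.1 CPM with a median of 61.56 CPM, and spok stayed at or below 0.999 CPM in the 9 sorted-cell libraries of the main table. Mitochondrially encoded transcripts summed to 10.2 to 45.2 CPM in 13 whole-disc libraries, 1 of them a control, and to 425 to 3726 CPM in the other 45, a split made after the data were seen.

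**Figure D5:**
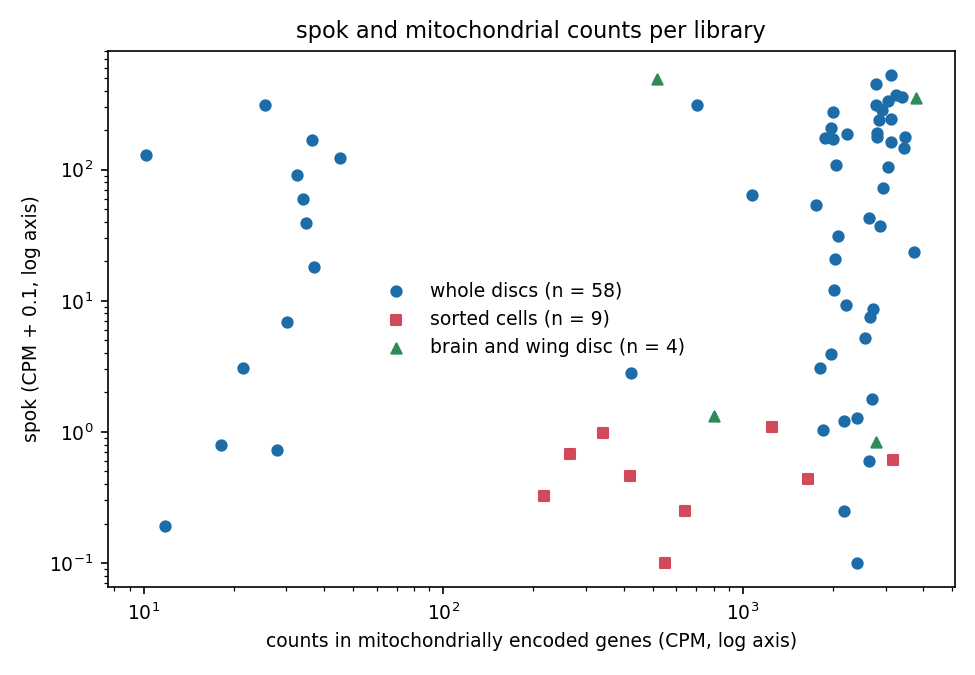
CPM of spok, with the small constant given on the axis added, against CPM of mitochondrially encoded transcripts (log axes) in 58 whole-disc libraries, 9 libraries of sorted cells and 4 of brain or wing disc, 1 point per library. Whole discs range up to 525.1 CPM of spok, whereas sorted cells stay at or below 0.999 CPM.

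The onecut mutant, 1 library, was compared with the 2 wild-type eye-antennal libraries of the same table to find genes that differ in this mutant of a Cut-homeodomain factor. The onecut gene (FBgn0028996) fell by 2.66 ± 0.19, from 145 ± 17.4 to 22.9 CPM (adjusted p = 0.0395). Among the largest falls were genes known from other tissues: the fat body lipoprotein gene Rfabg (FBgn0087002) fell by 7.08 ± 0.31, from 1483 ± 269 to 11 CPM, the larval serum gene Lsp1gamma by 6.40 ± 0.28, and the ring gland gene spok by 4.35 ± 0.22, from 337 ± 44.8 to 16.5 CPM. The synaptic genes Syt1 (-1.99) and cpx (-2.74) were the members of 20 neuronal genes that fell, or 17 adjusted over the list alone, with a median of -1.23. The photolyase gene phr (FBgn0003082) rose by 2.49 ± 0.18 and proPO-A1 by 2.28 ± 0.21. Glial genes held 3 falls among 12, or 6 adjusted over the list alone, Hox genes 1 among 7, or 5, and muscle genes 1 among 14, or 2. Fat body genes held 1 fall among 7, or 2 adjusted over the list alone, and neuroblast genes 0 among 8, or 4. Retinal determination genes had a median of 0.52 and ribosomal protein genes 0.51, each with 9 rises adjusted over the list alone and 0 over all genes. For these onecut lists the adjusted p = 0.8206 with an estimated correlation. Over the 58 whole-disc control and perturbed libraries spok ran from 0 to 525.1 CPM. Whether the falls of fat body, ring gland, neuronal, glial, Hox and muscle genes follow from onecut or from tissue dissected with the discs was not tested. In all 6 genes rose and 74 fell, 80 of 8786. The fit had 1 residual degree of freedom, and in simulated data of this design 45 unchanged genes were called; the count was 37 with DESeq2 size factors, 804 by DESeq2 and 0 with no filter on low counts.

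Cells sorted by eya expression had 1 column per sign, so ratios carry 95% counting intervals and no test. One gene, CG11210 (FBgn0033259), took 1126640 of 5186557 counts in the positive column, 21.7% (exact binomial interval 21.7 to 21.8%), and 241 of 8341727 counts in the negative one. Ratios were computed without this gene. Retinal genes were higher in the positive column: eya at a ratio of 13.6 (12.3 to 15.2), so at 12.0 (10.3 to 14.1), gl at 136 (102 to 186) and sev at 236 (158 to 369). Antennal and blood cell genes were lower, with Dll at 0.195 (0.166 to 0.227) and Pxn at 0.0812 (0.0385 to 0.152). The photoreceptor list had a median log2 ratio of 2.61, above that of every one of 10000 random lists, and the antenna list -2.24, below all of them. Lists of other tissues stood as far out: the fat body list had 4.22, above every random list, and the hemocyte list -2.40, below all of them. Ribosomal protein genes had a median of -0.81.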

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

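Among the tests in this part, those on the correlation of ring gland genes, on spok, dib and sro in sorted cells and on the number of RNAi targets above controls were chosen only after the result was seen, and the others before. In the 6 controls, 4 of 61 values tested had 1 library far from the rest, where chance alone gives about 1 in 20, or 3.05. The ecdysone and age list averaged 6.603 on the log2 scale in the ato-Gal4 driver library, against 5.982 to 6.184 in the other controls. The phototransduction list averaged 2.695 in the RAL-80 wild type, against 2.04 to 2.263. The level of mam was 8.141 in the sens-Gal4 with UAS-GFP library, against 8.658 to 8.731, and that of rn was 7.723 in the GMR-Gal4 driver library, against 6.341 to 6.744.

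Signals also appeared in data outside the main comparisons. In the GMR-Gal4 with UAS-GFP library the heat shock list averaged 8.840, above 4.167 to 5.15 in the controls and inside the 8.075 to 10.14 of the sorted cells. Its Notch response list averaged 7.232, above 5.109 to 5.505 in the controls and inside the 5.761 to 7.41 of the sorted cells. In the eya-positive column the gene CG11210 took 21.72% of counts.

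Ring gland hormone genes differed widely over whole-disc libraries, with spok at 0 to 525.1 CPM and a median of 61.56 over 58 libraries. The 6 genes moved together, with a median rank correlation of 0.899 (0.7615 to 0.9715 over 15 pairs), which is consistent with varying amounts of ring gland or brain tissue in the dissected material. Expression of spok by disc cells is argued against by the sorted cells of the main table, where spok reached at most 0.999 CPM (1.74 CPM in the eya-positive column), but dib and sro reached 11.69 and 11.68 CPM there, above their whole-disc medians of 5.219 and 9.83, and their expression by disc cells stays open. The rank correlation between spok and total counts was -0.286, in size below the limit set beforehand for a role of library depth. No p was computed for it, so a weak relation of spok with depth stays open. The design names no biological difference for the spread of spok. Which tissue the RNA came from stays open, since the brain libraries held spok at 354.6 to 494.9 CPM.

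Few genes were called for reduced glass when the RNAi library was included. Leaving out the ato-Gal4 control raised the count from 4 to 40 and the m4-Gal4 control to 9, so spread between controls may account for part of it, but leaving out any of the 4 others gave 0 or 1, and leaving out the RNAi library gave 193. A weak knock-down in the RNAi library cannot be told apart from it: the level of gl there was -0.28 ± 0.31. The 77 genes that fell in the mutant stocks had a median of -0.462 there, which decides nothing, since the stocks and the RNAi library were set against the same controls. In a fit of the 9 libraries alone the real split gave 0 calls against 3 for the highest other, and as any split gives at least 0, the 84 of 84 splits with as many say nothing about chance.

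Target genes stood above the controls in 4 libraries taken as RNAi, 3 by their titles and that of slp1 by the TRiP line in its genotype alone. An effect of the Gal4-7 driver line is argued against for Lim3 and sens-2, because their own libraries exceeded the highest other Gal4-7 library by at least 3.26 on the log2 scale, with Lim3 at 238.9 CPM against 13.61 to 24.1 in 4 others. Reads from a hairpin transgene could give such values and cannot be told apart from higher expression with counts per gene, which hold no read positions. A wrong label of these libraries was not tested.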

How the results depend on the processing

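The tests on 4 controls, on a term for few mitochondrial counts, on variance-stabilized values with 4 controls, on driver libraries in place of wild-type discs and on relations within mitochondrial sets were chosen only after the data were seen. Of named-gene values under the alternatives run, 2211 kept direction and side of the threshold, 432 were weaker, 10 stronger and 1 reversed; for targets, with DESeq2 size factors and with only the wild types as controls, the numbers were 77, 2, 4 and 1, and by rank 16 of 42 targets passed against 20. For relations, without the 2 farthest and without the glass libraries, 20 kept, 1 was stronger and 1 reversed. The following shares cover only the called genes that the naming rule picked, not all called genes. Past the threshold under every alternative run were 41 of 67 for eye-antennal against wing disc, 56 of 63 for wing disc against brain, 1 of 1 for Optix and 2 of 5 for Dfd. None held for eye-antennal disc against brain (0 of 62), GMR cells (0 of 47), glass reduced (0 of 2), glass overexpressed (0 of 3), toy (0 of 1), danr (0 of 2) and onecut (0 of 22). With 1 library in each arm, as for sens cells, 10% of 4-fold rises were recovered in simulated data. Not run were alternatives for the eya columns, which have 1 column per sign, and for the gene calls of the glass mutant stocks alone. Leaving out onecut libraries was not run either, as it leaves no residual degrees of freedom. Variance-stabilized values for the wild-type eye-antennal discs were not analysed here. Unless a setting tests fewer libraries, the cause was not tested.

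With DESeq2's Wald test the counts were 745 for glass reduced, 115 for glass overexpressed, 677 for toy, 44 for Optix, 46 for so, 681 for Dfd, 298 for lz, 580 for danr, 432 for side RNAi, 2501 for eye-antennal disc against brain, 1168, 332 and 537 for GMR, sens and chp cells, and 804 for onecut. With only the 2 wild-type libraries as controls they were 35 for glass reduced, 2 for glass overexpressed, 2 for toy, 1 for Optix, 0 for so and 9 for Dfd, and eya in the eya RNAi library turned to 0.0987. With GMR-Gal4 and UAS-GFP added to the controls glass reduced had 16, and the fold of so, so overexpressed against controls, turned to -0.08513. With all whole-disc libraries of other targets among the controls, glass reduced had 437 and glass overexpressed 169. In fits of only the compared libraries glass reduced had 0, glass overexpressed 2 and eye-antennal against wing disc 673. With 4 controls the counts were 1 for glass reduced, 0 for glass overexpressed, 1 for Optix, 0 for so and 3 for Dfd, and with limma on variance-stabilized values of 4 controls 1 for glass reduced and 1 for glass overexpressed. With a term for few mitochondrial counts they were 1, 0, 1, 2 and 0 for glass reduced, glass overexpressed, so, Dfd and danr. With 4 driver libraries as eye-antennal discs the count against brain was 2861. Without a filter on low counts sens had 55 and onecut 0, and with DESeq2 size factors onecut had 37. With the title number as a block GMR cells had 2319 genes. Deviations from the mean of each sign had a correlation of 0.3087 over genes between libraries with the same number. With 2 libraries per sign the other pair only mirrors this value, so the number is not shown to pair them. With an estimated correlation 0 of 123 list calls outside the single perturbed libraries and the glass mutant stocks held, with a lowest adjusted p of 0.1146, while DESeq2 size factors called 157 lists, 121 of them also in the first set. Within libraries with few mitochondrial counts 3 of 11 relations passed, those of peb, eya and toy, while gl, ato, sens, so, ey and lz no longer did (unadjusted permutation p = 0.287, 0.68, 0.06628, 0.074, 0.02606 and 0.3198), and that of ro turned to -0.0156 without the 2 farthest libraries.

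Leaving out 1 library at a time, the counts ranged from 598 to 918 for eye-antennal against wing disc, 0 to 1036 for eye-antennal disc against brain, 2382 to 2670 for wing disc against brain, 0 to 2135 for GMR cells, 0 to 193 for glass reduced, 1 to 1383 for glass overexpressed, 1 to 5 for toy, 1 to 12 for Optix, 0 to 3 for so, 5 to 334 for Dfd, 0 to 2 for lz and 3 to 9 for danr. A group left with 1 library was assumed to vary like the others.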

Other observations

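The comparison of nuclear respiratory genes between mitochondrial sets, the fits with 4 controls and with a term for few mitochondrial counts, and the ring gland and neuronal list correlation were tests chosen only after the data were seen. Further genes changed in single perturbed libraries. In the library of repo overexpression, the targeted glial homeobox gene repo rose by 3.45 ± 0.19 and the photoreceptor myosin gene ninaC by 3.33 ± 0.44. The dac overexpression library had the antimicrobial peptide gene Dro at 7.32 ± 1.18 (adjusted p = 0.03362), in 6 calls that became 1 with 4 controls and 3 with a term for few mitochondrial counts, and the library labelled tll RNAi had the blood cell genes proPO-A1 at 4.17 and CG8193 at 4.36. In the Kr[If-1] stock the synaptic genes Syn, n-syb and brp lay at -3.88, -3.01 and -3.00, and the protease gene ru at -5.93 ± 0.77.

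Between the 13 whole-disc libraries with few mitochondrial counts and the 45 others, 19 nuclear genes of the respiratory chain differed by a median of 0.0761 on the log2 scale. The glass overexpression libraries both lie in the low set.

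The GMR-Gal4 with UAS-GFP library had a fat body list average of 1.033 against 6.282 to 10.24 in the controls. Over the 58 whole-disc libraries, the averages of the ring gland and neuronal lists had a rank correlation of 0.3853.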
